A study of Gallus gallus with 4 samples.

How the data were processed

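Liver of coloured broiler chickens was profiled on 4 one-colour Agilent oligonucleotide arrays, 2 per group. Per the labels, each chick lived in its own cage with free access to feed and water for a feeding trial of 35 days. Starter feed was given up to week 4 and finisher feed after that. Total RNA came from 50 mg of tissue, RNA of birds in a group was brought to one concentration and pooled, and 200 ng was labelled with the dye Cy3. The design text names 4 to 5 birds slaughtered per group at 5 weeks and a pool divided in duplicate. For group 2 the labels name different sexes for the arrays. The median of 416 Z-linked probes against the other arrays was 0.50 on group 2 replicate 1 and -0.16 on replicate 2. These values argue against a single divided pool for the group 2 arrays, which may hold different birds. P-values therefore measure only the spread between these samples. That spread may be technical in group 1 and may include differences between birds in group 2. The labels give no number of birds per array beyond the sexes they name.

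The scanner files hold one row per spot with its intensity on a linear scale, which per the file headers came from Agilent Feature Extraction 11.5.1.1, with background already subtracted in the processed column. The deposited series table holds log2 values made by the authors. Set against the scanner values, each of its columns equalled the log2 intensity minus the array's 75th percentile, centred on each probe's median over the 4 arrays (Pearson r across probes 1 on every array after rounding). Its column medians were 0.084, 0.016, -0.094 and -0.022 for replicates 1 and 2 of group 1 and then of group 2. The scale, centring and direction of that table were thus settled from the values, and it served as an alternative source of the same signal.

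The main values were log2 of the processed intensity minus each array's 75th percentile over 43803 spots that are not controls. That percentile was 978, 1449.6, 1170.03 and 1278 intensity units for the same order of arrays. Spots marked as non-uniform or population outliers were set to missing, 25, 12, 8 and 13 per array, and no spot was saturated. The 5 spots of each of 50 replicated probes were averaged, which left 43603 probes. A probe was kept where its signal was well above background on both arrays of at least 1 group, which left 33869 probes, 33868 of them with enough values to test. Arrays carry no read depth, and their number limits the precision.

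Probes were named through the unversioned RefSeq accessions in the array files, matched to a gene table of the assembly GRCg7b. Of all probes, 11935 (27.4%) were named, for 5382 genes, and the other 31668 were counted as probes without a gene name. The array design was drawn on another build (galGal3), so the table served for names and chromosomes only and no coordinates are given. A gene was represented by its brightest kept probe, for 4872 genes, of which 1714 had a single kept probe.

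Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as group 1 minus group 2, since the design text takes the low group as the control. P-values were adjusted with Benjamini-Hochberg over all tested probes, and an adjusted p under 0.05 counted as a change. The moderated test had 2 residual and 2.60 prior degrees of freedom. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.333. Where a probe was not well above background on both arrays of one group, the difference is given as at least N-fold. Such a bound sets the mean of the brighter group against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

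The 27 gene lists were written before the data were examined, and 26 had at least 5 measured members. They cover fatty acid and triglyceride synthesis, fatty acid oxidation and ketogenesis, cholesterol synthesis and uptake, lipoprotein particles, and bile acid synthesis and drug metabolism. They also cover glycolysis and gluconeogenesis, oxidative phosphorylation, the citric acid cycle, amino acid and uric acid metabolism, and the growth, insulin and thyroid axis. Others hold acute phase and complement genes, cytokines and chemokines, interferon response, unfolded protein and heat shock response, antioxidant defence, cell cycle and ribosomal proteins. Marker lists stand for erythroid cells, T and B lymphocytes, macrophages and heterophils, endothelial and stellate cells, bile duct epithelium, pancreas acinar cells, skeletal muscle, adipose tissue and hepatocytes, and 1 list holds W-linked genes. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. A list of intestinal genes was added after the largest differences had been seen.

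Genes were named by a rule fixed beforehand, leaving out symbols made of a LOC number, a clone, an accession or an open reading frame. It takes the 10 largest differences in each direction among genes past the test, well above background on all 4 arrays, with no overlap between groups. It also takes up to 2 members per list and direction with the smallest p past the threshold, or else the 1 with the smallest p. Up to 5 genes per direction with the largest at-least-N-fold bound and each measured W-linked gene complete it. List members named in the text beyond this rule, such as FASN or ALB, were chosen after their values were seen.

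The steps were tested on simulated data for group 1 against group 2 over 33841 probes. With 200 changed probes, 74 of the 100 shifted by 4 log2 units and 0 of the 100 shifted by 2 were recovered, with 0 false calls. With 4000 probes shifted by 2 log2 units, 82.1% were recovered and 4.12% of the calls were false. The simulated noise was independent between arrays, with 1 variance per probe in both groups. On the real arrays the SD of the difference was 0.42 within group 1 and 0.79 within group 2. The simulated share of false calls therefore need not hold for the real calls. When acute phase and complement genes were shifted by 2 log2 units, camera called that list and 1 of the others, the hepatocyte markers, which share members with it. Alternatives covered the scaling, the background correction, the source of the values, the filter on dim probes, the flagged spots and the variance model. They also covered the test, a replicate block, each array left out in turn, the sex chromosomes, the mean over a gene's probes and the correlation between genes. The background correction by normexp with an offset of 50 was followed by quantile normalization, and it used the median signal, because the files given here held no mean-signal column.

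All 4 arrays lay on 1 slide, with group 1 in columns 1 and 2 and group 2 in columns 3 and 4, so position on the slide and group cannot be told apart.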

Results

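The study compared the liver of coloured broilers of 35 days from 2 groups that differ in feed efficiency. Feed efficiency is the growth a bird gains per unit of feed. Group 1 is labelled high and group 2 low, each with 2 arrays of pooled birds. The labels give the words high and low both to feed efficiency and to residual feed intake, the feed eaten beyond what size and growth predict. High residual feed intake usually means low efficiency, so the labels do not settle which group used its feed better, and the groups keep their numbers here. Signals well above background made up 78.2% and 80.2% of probes on the group 1 arrays, and 74.9% and 72.3% on those of group 2. The group 1 arrays correlated at r = 0.989 across probes and the group 2 arrays at r = 0.966, against 0.931 to 0.946 for the 4 pairs between groups. The SD of the difference between the arrays of a pair was 0.42 log2 units within group 1, 0.79 within group 2 and 0.98 to 1.09 between groups.

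The first question was which liver genes differ between the groups. Some genes best known from intestinal epithelium stood far higher in group 1. On a list of intestinal genes written after the largest differences were seen, 21 of 47 measured members were called higher and the others were not. RBP2, which binds retinol in the cells that absorb it, was at least 199.5-fold higher (limma, adjusted p = 0.00618), and FABP2, the intestinal fatty acid-binding protein, at least 95.7-fold higher (adjusted p = 0.00692). CDX2, a transcription factor of the intestinal lining, was at least 31.6-fold higher (adjusted p = 0.0144). In group 2 the biotin-binding protein avidin (AVD) and CYP7A1, the rate-limiting enzyme of bile acid synthesis, were higher, with log2 differences of -4.31 ± 0.25 and -3.42 ± 0.23 (group 1 minus group 2, SE, n = 2 arrays per group). Stearoyl-CoA desaturase (SCD), which makes monounsaturated fatty acids, differed by -3.03 ± 0.52.

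Of 4872 genes, 280 were higher and 191 lower in group 1 (limma with Benjamini-Hochberg), and 276 and 189 of them differed at least 2-fold. Over all 33868 tested probes, 2506 were higher and 1295 lower. At an unadjusted p under 0.05 the genes numbered 930 and 609. In 68.1% of genes the arrays of one group lay wholly above those of the other. Independent arrays without any group difference would give 33.3%. Arrays that share a divided pool or a place on the slide can exceed that share, so the excess does not measure an effect of feed efficiency. Among the called genes with further probes, those probes all had the same sign for 145 of 160 higher genes and 87 of 105 lower genes. The median log2 difference of all genes was 0.14, and -0.08 with arrays scaled on their medians. The share of called genes that were higher in group 1 was 59.45%, but 51.5% after quantile normalization and 40.2% with median scaling. Without group 1 replicate 1, 0 genes passed the test and 336 higher and 224 lower genes had an unadjusted p under 0.05. Without group 1 replicate 2, 0 passed as well, with 434 and 281 genes at that level. Without group 2 replicate 1, 607 and 429 genes passed, and without group 2 replicate 2, 721 and 420. Group and position on the slide cannot be told apart.

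Among genes measured on all 4 arrays, the largest rise was that of CKMT1B, a mitochondrial creatine kinase, with a log2 difference of 5.04 ± 0.24 (limma, adjusted p = 0.0144). GUCA2B, the precursor of the gut peptide uroguanylin, followed with 4.35 ± 0.39 (adjusted p = 0.0212). The receptor kinase GRK4 (3.39), the proton channel HVCN1 (3.18), angiotensin-converting enzyme ACE (3.10) and the secreted protein DKK3 (3.09) also rose. HSD3B1, a steroid dehydrogenase, differed by 3.06, the early response factor EGR1 by 3.05, APIP of methionine salvage by 3.02 and the BMP antagonist CHRDL1 by 2.998. ANGPT1L was at least 106.5-fold and the tight junction gene CLDN10 at least 11.47-fold higher in group 1. On the lower side stood V-BG (-3.81), the mitochondrial translation factor MTIF3 (-3.59) and the drug-metabolising cytochrome CYP2C18 (-3.59). The 2 probes of the acyl-CoA thioesterase ACOT9 were called in opposite directions, the brighter with -3.84 (adjusted p = 0.0281) and the other with 1.51 (0.04975). GCHFR, a regulator of GTP cyclohydrolase, differed by -3.17, TNIP2 by -3.10 and the surfactant protein gene SFTPA1 by -3.07. RPE65 and ANKDD1A were at least 3.275-fold and 2.42-fold higher in group 2, and PTGER3 at least 1.39-fold. PHACTR3, with a bound of 1.585-fold, did not pass the test (adjusted p = 0.143). In all, 87 genes were not well above background in group 2 alone and 5 in group 1 alone. Over all probes, signals well above background were also more frequent on the group 1 arrays (78.2% and 80.2%) than on those of group 2 (74.9% and 72.3%). These counts may therefore follow detection on the whole array.

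**Figure D1:**
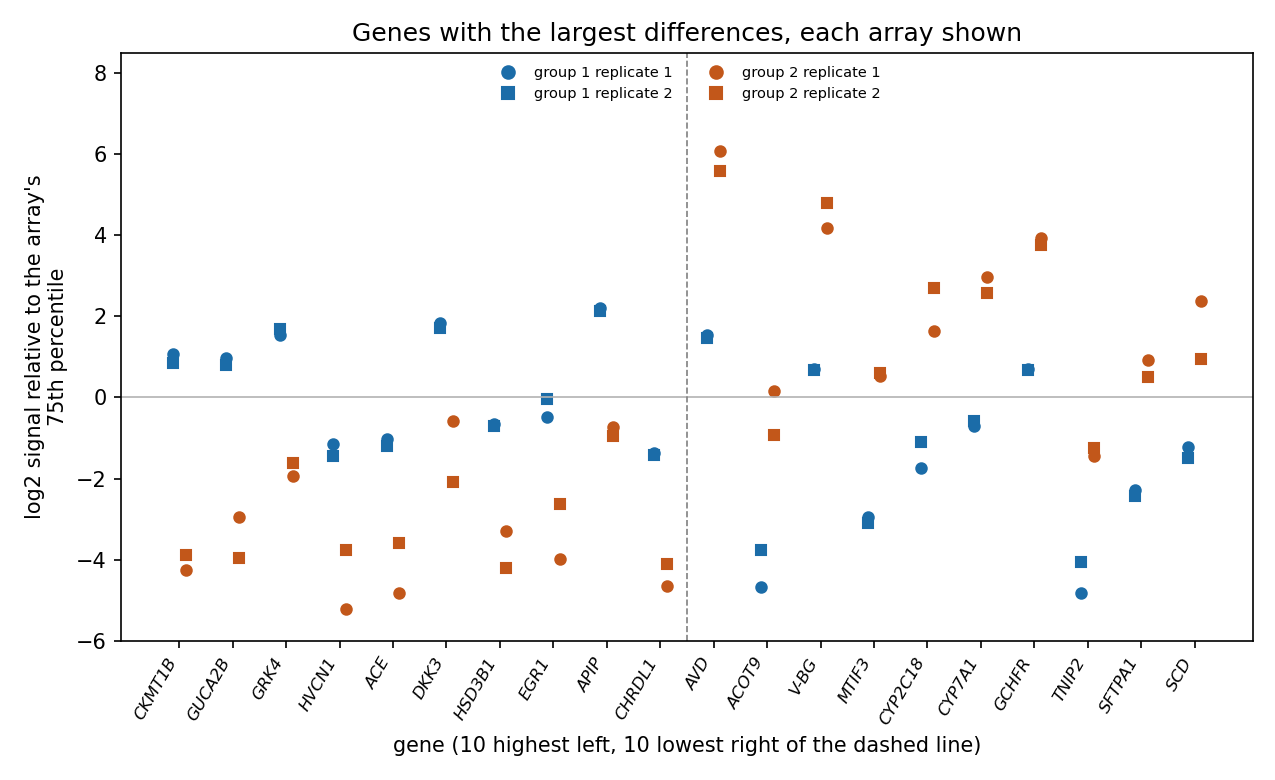
Level of the 10 genes with the largest rise and the 10 with the largest fall in group 1, on each of the 4 arrays, read on the gene's brightest probe, as log2 signal relative to the array's 75th percentile. Circles are replicate 1 and squares replicate 2, with group 1 in blue and group 2 in orange. The group 1 arrays lie close together for most genes, while those of group 2 spread more, as for HVCN1 at -5.21 and -3.77.

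The second question was which gene groups moved. Bile acid synthesis and drug metabolism was the only one of the 26 tested lists called lower in group 1 (limma camera, adjusted p = 0.0235, and adjusted p = 0.738 with an estimated correlation). Of its 18 measured members 5 fell and 1 rose, or 7 and 2 when adjusted over the list alone, and the median log2 difference was -0.73, or -0.29 without group 2 replicate 1. CYP7A1, CYP2C18, the nuclear receptor NR0B2 (-1.56), AKR1D1 of bile acid synthesis (-1.30) and the glutathione transferase GSTA2 (-1.22) fell, and the sulfotransferase SULT1B1 rose (1.52). The list's call was lost after quantile normalization (adjusted p = 0.0862), with median scaling (0.102) and with normexp followed by quantile normalization (0.0589). Oxidative phosphorylation was called higher (adjusted p = 0.0162, and adjusted p = 0.738 with an estimated correlation), with a median of 0.49 over 32 members and 28 of them above 0. Cytochrome c (CYCS, 1.03 ± 0.20) was its only member past the test, and adjusted over the list alone 0 were. That list was not called without group 1 replicate 1 (adjusted p = 0.0516) or without group 2 replicate 1 (0.0719).

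In lipid metabolism SCD alone fell among 17 genes of fatty acid and triglyceride synthesis, 4 fell when adjusted over the list alone, and the median was -0.0013 (-0.30 to 0.09 with 1 array left out). FASN, fatty acid synthase, had a log2 difference of -1.14 (adjusted p = 0.0659) and its regulator SREBF1 one of -1.17 (0.0577). CPT1A, which brings fatty acids into mitochondria for oxidation, rose by 2.18 ± 0.29 and was the 1 called member among 19 genes of fatty acid oxidation and ketogenesis, where the median was 0.30 (0.16 to 0.36 with 1 array left out). Adjusted over the list alone 1 was called too. None of 12 genes of cholesterol synthesis and uptake passed, over all probes or adjusted over the list alone, with a median of -0.45 (-0.90 without group 2 replicate 1 and 0.09 without replicate 2), and HMGCS1 came nearest at -0.91 (adjusted p = 0.057). APOV1, a yolk apolipoprotein that the liver makes under oestrogen, rose by 8.70 ± 0.48, with 1 of the 2 group 2 arrays well above background, and was the 1 called of 15 lipoprotein genes by either adjustment. APOA1 (0.12), APOB (-0.07) and VTG2 (0.51) did not pass, and the list's median was 0.13 (-0.12 to 0.39 with 1 array left out).

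Among glycolysis and gluconeogenesis genes 1 of 23 fell, lactate dehydrogenase LDHA (-1.76), and 3 when adjusted over the list alone. In the citric acid cycle SUCLA2 was the 1 member of 16 to rise (1.79), with 2 adjusted over the list alone and a median of 0.58. Glutamine synthetase GLUL rose (1.504) and PPAT, an early enzyme of purine synthesis, fell (-1.49), the 2 called of 29 genes of amino acid and uric acid metabolism by either adjustment. In the growth, insulin and thyroid axis 3 of 25 genes rose and 2 fell, or 5 and 2 adjusted over the list alone. IGFBP2, a carrier of insulin-like growth factors, differed by 2.90, ghrelin (GHRL) was at least 2.84-fold higher, and the receptor IGF1R differed by 1.18. SOCS1 (-2.12) and CISH (-1.55), inhibitors of cytokine signalling, fell. IGF1 (0.16), GHR (0.16) and DIO1 (-0.20) did not pass.

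In immune lists, AVD was the 1 called of 19 acute phase and complement genes by either adjustment. Of 28 cytokine and chemokine genes 3 fell by either adjustment, TNFSF10 (-2.46), the interleukin receptor IL1R1 (-2.01) and CCL20 (-1.58). Of 15 interferon response genes 2 fell, B2M (-2.33) and SOCS1, and 1 rose, the MHC class I gene BF1 (2.02 on its brightest probe). The other 4 probes of BF1 differed by 1.02 to 1.23 and did not pass (adjusted p = 0.0888 to 0.174). Adjusted over that list alone 3 fell and 1 rose, and its median was -0.86 with camera adjusted p = 0.107. Without group 2 replicate 2 these were -1.37 and 0.0034, and without group 2 replicate 1 they were -0.04 and 0.583. B2M encodes the partner chain of MHC class I molecules, and its 3 probes differed by -2.33, -2.57 and -2.27. The chaperone genes PDIA4 (-1.16) and CRELD2 (-1.07) fell among 27 genes of the unfolded protein and heat shock response, and MGST3 (-1.20) among 28 of antioxidant defence, with 0 in both lists adjusted over the list alone. KIF23, needed for cytokinesis, fell (-2.83) and MCM3 rose (1.28) among 30 cell cycle genes, the same number adjusted over the list alone. None of 43 ribosomal protein genes passed by either adjustment, with a median of 0.23 (0.06 to 0.40 with 1 array left out), and RPS6 came nearest (-0.50). For glycolysis, amino acid metabolism and antioxidant defence the median lay above 0 (0.19, 0.05 and 0.12) while camera gave the direction down, and for acute phase genes the median (0.05) lay above 0 while the mean (-0.17) and camera pointed down. With 1 array left out these 4 medians ranged from 0.0025 to 0.31, -0.05 to 0.15, -0.09 to 0.15 and -0.17 to 0.22.

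Markers of other cells moved with the groups too. Erythroid markers had a median log2 difference of 2.11, or 1.24 without group 2 replicate 1, and all 11 lay above 0, RHAG (3.85, well above background on 1 group 2 array), the anion exchanger SLC4A1 (2.11) and the haemoglobin chain HBBR (2.67) past the test. Of 19 endothelial and stellate cell markers 10 rose, among them the collagens COL1A2 (2.19 ± 0.21) and COL5A1 (2.16 ± 0.21), and the median was 1.12. Among 17 T and B lymphocyte markers CD74 alone passed (1.38), the median was 0.97 and 16 lay above 0. Camera called these 3 lists higher in group 1 (adjusted p = 0.00325 each, and adjusted p = 0.738 each with an estimated correlation). Adjusted over the list alone 8, 11 and 8 members rose. Of the 26 lists, fry found 4 that moved on balance in one direction and 23 whose genes changed in either direction. The 4 were bile acid synthesis and drug metabolism (adjusted p = 0.00598), endothelial and stellate cells (0.0288), T and B lymphocytes and the growth, insulin and thyroid axis (0.0367 each). Erythroid markers (0.190) and oxidative phosphorylation (0.123) were not among them. Some intestinal genes moved with the groups as well. Of a list added after the largest differences were seen, 21 of 47 measured members rose in group 1. Of the 21 that had not been seen and that liver does not share, 4 rose and 0 fell. Among all genes 5.75% were called higher and 3.92% lower.

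Markers of hepatocytes, the main liver cells, gave 0 calls of 13 by either adjustment, a median of 0.06 (-0.19 to 0.27 with 1 array left out), a mean of -0.09 and the camera direction down. Albumin (ALB, 0.29), APOA1 and vitronectin (VTN, -1.41, adjusted p = 0.0884) did not pass. Of 15 macrophage and heterophil markers PTPRC rose (1.06) and LYG2 fell (-1.95), or 5 and 2 adjusted over the list alone, with a median of 0.58 (1.01 without group 2 replicate 1 and 0.38 without replicate 2). CLDN3 rose (1.46) and SPP1 fell (-1.29) among 8 bile duct markers, or 3 and 1 adjusted over the list alone. The pancreas enzymes CPA1 (1.22) and CTRC (1.82) rose among 10 markers, or 3 up and 1 down adjusted over the list alone, with a median of 0.94. The muscle genes MYL1 (at least 1.45-fold) and MYL3 (at least 2.44-fold) were higher and TNNC1 fell (-1.76) among 11 markers, with the same counts adjusted over the list alone. FABP4 rose (1.62), the 1 called of 9 adipose markers by either adjustment. Of the 69 named genes, SLC4A1, CD74, PTPRC, CPA1, CTRC, MYL3, FABP4, CRELD2 and MGST3 no longer passed after quantile normalization. SLC4A1, CD74, PTPRC, FABP4, CYCS and MCM3 did not pass with median scaling, and CPA1, CTRC, GHRL, MYL1, MYL3, PTGER3 and RPE65 did not with normexp followed by quantile normalization. Calls were lost for 29 of the 69 without the filter, for 13 with the replicate block, and for 64 without moderation or without either group 1 array.

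**Figure D2:**
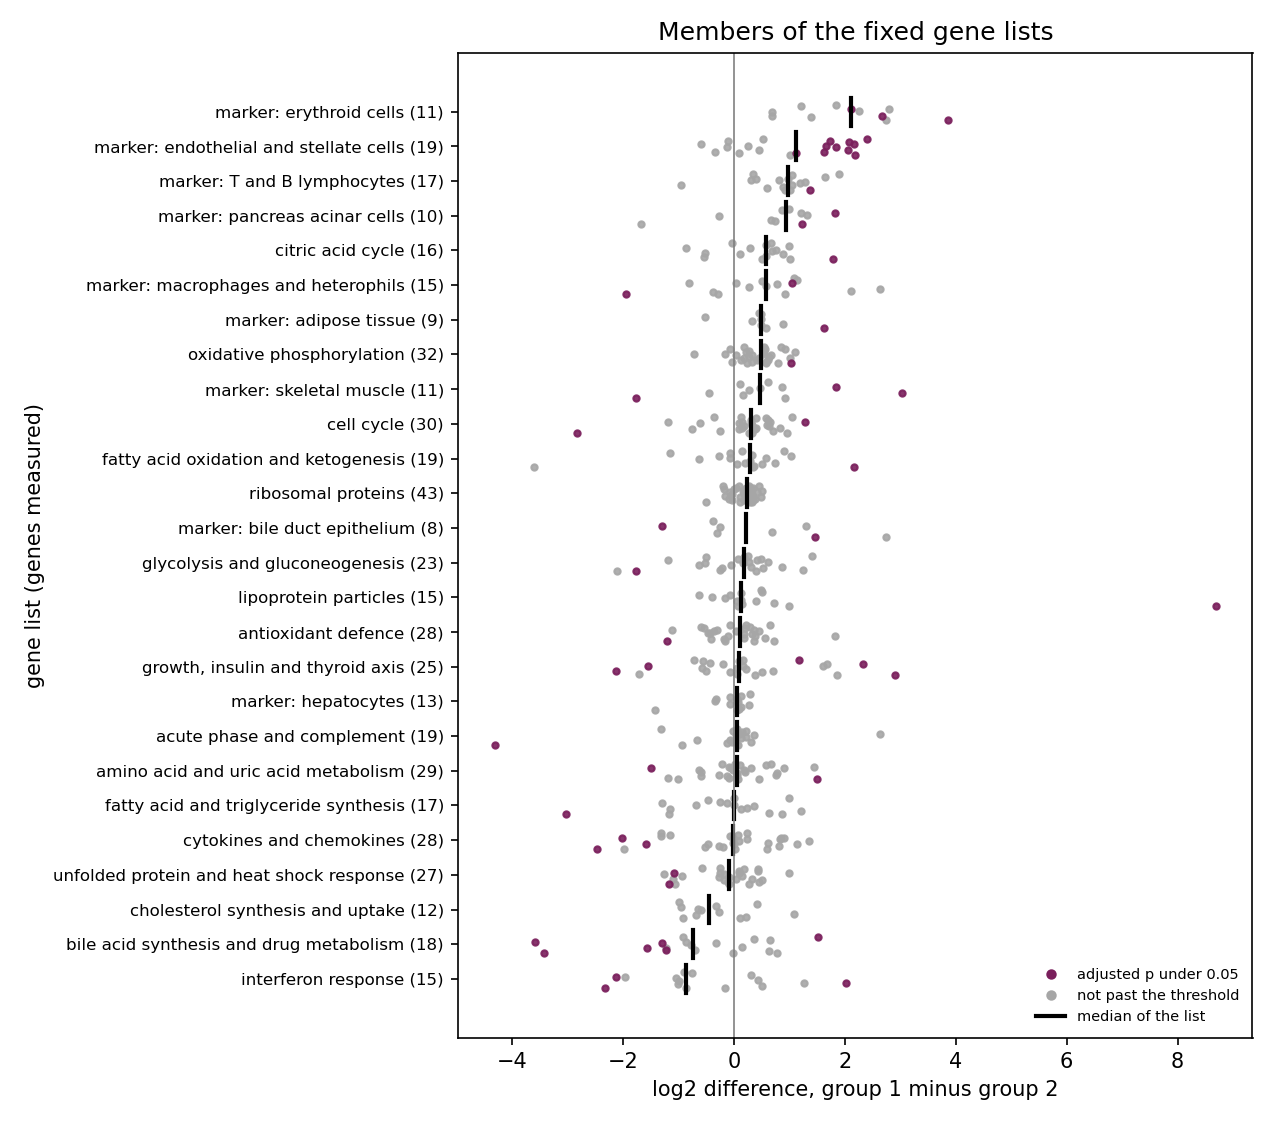
Log2 difference, group 1 minus group 2, of each measured member of the 26 tested gene lists, with the number of genes in brackets. Purple points have an adjusted p under 0.05, grey points do not, and black bars mark the median of the list. Erythroid markers lie farthest to the right (median 2.11), and the interferon response farthest to the left (median -0.86).

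The labels name females for 3 arrays, and 1 male and 1 female for group 2 replicate 2. Hens carry the W chromosome and 1 Z chromosome, and cocks carry a pair of Z chromosomes. HINTW, a W-linked gene with many copies, was therefore read on each array with its 8 probes. On the array labelled group 2 replicate 1, for which the label names females only, HINTW was lower than the group 1 mean by a median of at least 500.4-fold, and by more than 8 log2 units for 5 probes, with the 1 probe not well above background there set to its bound. Its brightest probe differed by -1.25 only. On the array labelled group 2 replicate 2 the median was -0.29, a level of 81.7% of group 1. Z-linked probes (416) on the array labelled group 2 replicate 1 had a median of 0.50 log2 units against the other 3 arrays, above all 10000 random autosomal probe sets matched on expression, and autosomal probes one of -0.04. On group 2 replicate 2 the Z-linked median was -0.16. The 34 W-linked probes had medians of -0.91 and 0.51 on these 2 arrays. The array with the least W-linked signal is thus not the one whose label names a male. The difference of HINTW between the groups did not pass the test (brightest probe 0.64 ± 0.45, limma, adjusted p = 0.354).

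**Figure D3:**
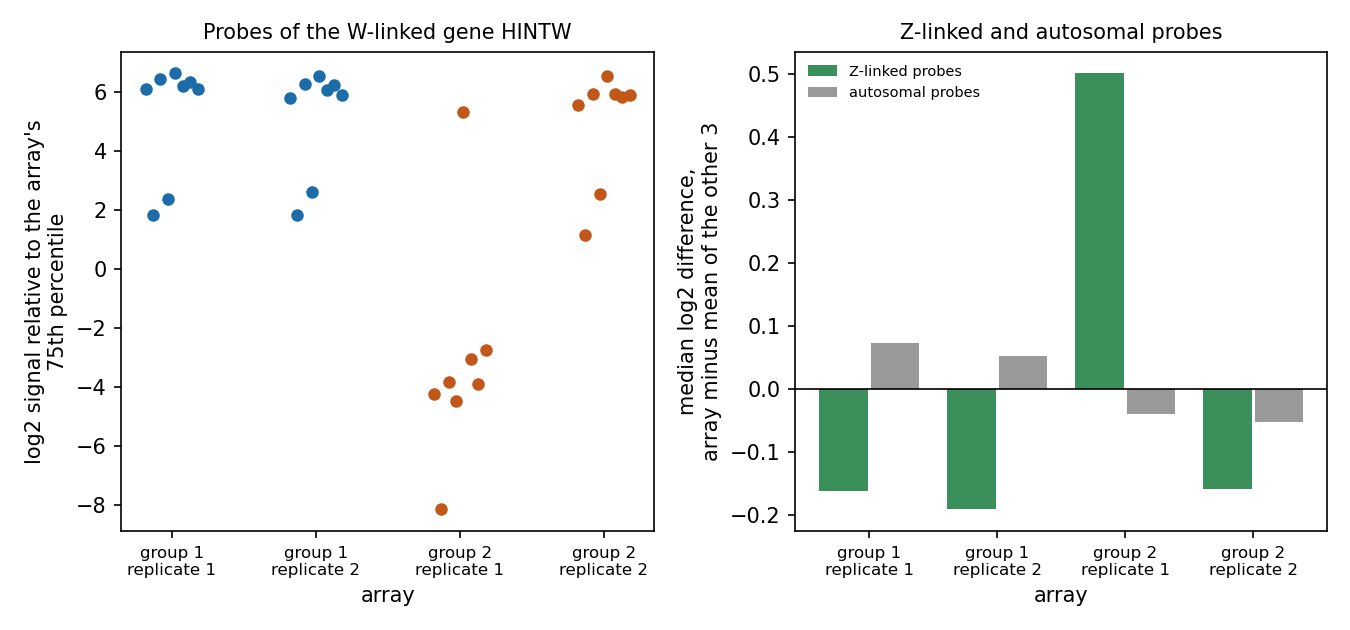
Left, log2 signal of the 8 HINTW probes on each array relative to the array's 75th percentile. Right, median log2 difference of 416 Z-linked (green) and autosomal (grey) probes, each array minus the mean of the other 3, where the array labelled group 2 replicate 1 stands at 0.50 and the others between -0.19 and -0.16.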

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

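The values for the array labelled group 2 replicate 1 on chromosomes W and Z and the median of all genes were added after the data were seen. With the authors' table and with flagged spots kept, all 12 group results stayed within 1.5 times or 1 SD of the reported ones, and 469 and 468 genes called there were among the 471. The authors' table holds the same scaled signal centred per probe, which leaves group differences unchanged, so its agreement was largely fixed in advance. Without probes on Z and W all 8 group results stayed within those limits. That setting keeps all autosomal genes, so it does not separate sex from group. The cause was not tested where a value moved, but some settings change what the test sees. No filter adds dim probes. Fewer arrays leave fewer degrees of freedom. With 1 array left out, the residual spread comes only from the pair of the other group. The SD of the difference was 0.79 in the group 2 pair and 0.42 in the group 1 pair. Calls were lost without a group 1 array and rose without a group 2 array, as that spread implies. Precision is limited by 2 arrays per group and, for dim genes, by signal over background.

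Leaving out 1 array gave 0 to 5847 probes higher and 0 to 3113 lower, 0 to 721 genes higher and 0 to 429 lower, 0 to 576 and 0 to 335 at least 2-fold, and 1 to 2 lists called lower. The second was cholesterol synthesis and uptake without group 2 replicate 1 (adjusted p = 0.0115) and interferon response without group 2 replicate 2 (0.0034). Both group 1 arrays gave the zeros in probes and genes, and the lone array is assumed to vary like the other group. The linear model without moderation called 0 probes and 0 genes either way, 0 at least 2-fold and 0 lists lower, with 700 higher and 520 lower genes at an unadjusted p under 0.05. The replicate numbers did not pair the arrays (correlation of deviations 0.033), and with the replicate block 725 probes and 111 genes were lower, 111 of them at least 2-fold, and 189 genes were higher.

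Quantile normalization gave 1574 probes higher, and median scaling 2012 probes and 302 genes lower, 296 at least 2-fold. Normexp followed by quantile normalization gave 2285 probes and 345 genes lower, and each of these 3 called 0 lists lower. Without the filter 926 probes were higher and 315 lower, and 102 and 54 genes, 102 and 54 of them at least 2-fold. Trend and robust moderation gave 1962 probes lower, 433 genes higher and 319 lower. The mean over a gene's probes gave 446 and 309 genes and 2 lists lower, the second again cholesterol synthesis (adjusted p = 0.0297). With an estimated correlation 0 lists were called either way, and the smallest adjusted p by camera was 0.738. The estimate lay near or below the preset 0.01 for bile acid (-0.048), endothelial (0.011) and lymphocyte (0.0056) genes. Genes moving together do not account for those lost calls. For erythroid markers (0.84) and oxidative phosphorylation (0.21) the estimate was higher.

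W-linked probes on group 2 replicate 2 had medians of 0.65 with median scaling, 0.44 with normexp and quantile normalization, 0.58 without a filter, 0.34 with all 4 arrays above background and 0.34 with the mean of probes. On replicate 1 these were -0.77, -0.67, -1.17, -0.48 and -1.25. Z-linked probes on replicate 2 had -0.068 with quantile normalization, -0.013 with median scaling, -0.061 with normexp and quantile normalization and -0.10 with the mean of probes. On replicate 1 they had 0.56, 0.64, 0.46 and 0.47, and 0.44 without a filter and 0.52 with all 4 arrays above background.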

Other observations

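LOC395159, the MHC genes and the genes that set the group 2 arrays apart were chosen after their values were seen. LOC395159, outside the naming rule, was at least 184.7-fold, 193.5-fold and 62.4-fold higher in group 2 on its 3 probes (limma, adjusted p = 0.00618, 0.00618 and 0.00894), none of them well above background on a group 1 array. The MHC class II gene BLB1 had log2 differences of 0.92, 1.05 and 2.30 on 3 probes, with adjusted p = 0.1885, 0.07405 and 0.0377 and DMB2 one of 1.21 (adjusted p = 0.0381).

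The arrays of group 2 differed from each other in several gene groups. The antiviral gene MX1 stood at 4.53 on replicate 1 and at -0.21 on replicate 2, against 1.15 and 1.19 in group 1. THRSP, a regulator of fatty acid synthesis, stood at 7.28 and 4.23, PDK4, which slows the use of glucose, at 1.35 and 3.72, and IGFBP1 at -0.16 and 2.22. All 12 measured genes of cholesterol synthesis and uptake were lower on replicate 1 than on replicate 2, with a median of -0.86. All 11 erythroid markers were lower as well, with a median of -1.54, and 11 of 15 interferon response genes were higher, with a median of 0.69. The arrays of group 1 differed by 0.06, 0.14 and -0.11 in those lists.

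Some of the tests reported here were chosen after the result was seen. These were the tests on the array labelled group 2 replicate 1 and on the share of hepatocytes with all arrays. The test on the called intestinal genes after quantile normalization was another. The list of 102 intestinal genes was also written after the largest differences were known. Of its 47 measured members, 16 had been seen by then and 10 are also used by liver or stand on another list. In all 21 rose and 0 fell, and of the 21 not seen before and not shared with liver 4 rose and 0 fell. Among the risers were GIP (4.88, well above background on 1 group 2 array), the sugar transporter SLC5A1 (2.66) and villin, VIL1 (1.26). FABP6 (-0.71), GATA5 (-1.15) and the peptide transporter SLC15A1 (0.25) did not pass.

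Higher scaled values of dim probes on the group 1 arrays are argued against only as the source of the size of the 21 called differences. After quantile normalization 20 of them, with 4 of the 5 not seen before, stayed past the test. The median of the 21 was 3.766 against 4.039 before (3.10 before with 11 dim genes at their bound). GATA4 alone lost its call, as its difference fell from 0.99 ± 0.20 to 0.56 ± 0.19. It was well above background on 1 group 2 array. The 21 genes were picked by their calls in the same data, so these values decide nothing about intestinal genes as a set. For the 21 genes that had not been seen and that liver does not share, that explanation stays open: their median of 0.64 lay at the 98.1 percentile of random lists matched on expression, but after quantile normalization it was 0.2936, inside the range of -0.31 to 0.40 that held 95% of such lists. The median of all 47 after quantile normalization, 0.62, decides nothing, since 16 of these genes had been seen before the list was written. Intestinal tissue in the group 1 RNA stays open and may be a candidate source for the called genes, and a difference between the groups in the liver itself was not tested.

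Male RNA on the array labelled group 2 replicate 1 stays open and may account for its low W-linked signal, since the Z-linked median of 0.50 was above the range of -0.10 to 0.03 of random autosomal sets. An exchange of the labels of both group 2 arrays alone is argued against, because a pool with a female would keep far more HINTW than the median of at most -8.967 found there, with the 1 probe not well above background set to its bound. A failed hybridization or scaling of that array is argued against by the W-linked median of -0.91, below the range of -0.24 to 0.20 of random autosomal sets as bright, while the autosomal median of -0.0402 decides nothing because the scaling holds it near 0. The Z-linked medians of 0.50 on group 2 replicate 1 and -0.16 on replicate 2 argue against a single pool divided over both arrays. Whether another sample took the place of replicate 1 was not tested. Of the differences within group 2, the interferon one set replicate 1 apart from group 1. That list's median was -1.375 without group 2 replicate 2 and -0.04 without replicate 1. The cholesterol one set replicate 2 apart instead, with 0.09 and -0.90. Erythroid markers lay below group 1 on either group 2 array, farther on replicate 1 (2.66 and 1.24). The cause of these differences was not tested.

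Markers of blood, vessel and lymphoid cells were higher in group 1 by camera at the preset correlation. Camera with an estimated correlation did not call them (adjusted p = 0.738 each), and fry did not call the erythroid list (0.190). For vessel and lymphoid markers the estimate (0.011 and 0.0056) lay near the preset 0.01, and no list at all passed at that setting. Their lost calls thus decide little. A lower share of hepatocytes stays open. The hepatocyte markers themselves showed no clear fall, with 0 of 13 called, a median of 0.06 and a mean of -0.09, but a small fall is not excluded. Erythroid and bile duct markers moved apart by 1.895 log2 units (95% bootstrap interval over genes 0.10 to 3.01) with all arrays. Without group 2 replicate 1 they moved apart by 0.744 (-0.66 to 1.94). The bootstrap resampled the 11 erythroid and 8 bile duct genes with the arrays fixed. Its interval therefore measures the spread between genes, not between birds or arrays. The erythroid genes also moved together (estimated correlation 0.84), so they are not 11 independent values. More blood in the group 1 RNA stays open too and may account for the erythroid part. All 11 erythroid markers were higher on each group 1 array than on each group 2 array, and the median gap between the lowest group 1 and the highest group 2 array was 1.103. Collagen and lymphocyte markers are not covered by that test, and a difference between the groups in the liver itself stays untested.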
